A study of Bos taurus with 6 samples.

How the data were processed

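Gene expression was measured in longissimus thoracis muscle, a large muscle along the back, of 6 castrated male cattle of the Japanese Black beef breed. Per the labels' protocols, the steers entered the study at 13 to 14 months of age, were fattened for 7 months on feed meant to give a daily gain of 1.0 kg, and were 20 to 21 months old at its end. The supplemented group of 3 steers received vitamin A by mouth each week at 296.8 IU per kg body weight, and the restricted group of 3 steers did not. Total RNA was extracted with Trizol and purified on RNeasy columns, and 100 ng of it was amplified and labelled with biotin for a 3 prime expression array of the Affymetrix GeneChip type, per the labels' protocols. Each array holds a different steer, so the p-values of single probe sets measure the spread between steers within a diet.

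The values are those the authors deposited, 1 table of 24128 probe sets on 6 arrays, and are taken here as log2 values because they run from about 5 to 13. The base of the logarithm, the background correction, the normalization and the summarization are not given in the sources used here. The deposited log2 values differ very little between arrays. The highest and lowest array of a probe set were a median of 6.77e-07 apart, 34 of the 24016 tested probe sets ranged over more than 0.01 and 1 over more than 0.1. Because the step that gave this narrow spread is not stated, a difference between the diets is not read as a fold change. Differences are given in deposited log2 units and in within-group standard deviations (SD) of the same probe set, which do not depend on a constant factor applied to that probe set. The sorted values of single arrays lay within 0.00911 of their mean, and the values were used as deposited. Array medians differed by 8.88e-06, which is more than the whole range of 85.9% of the tested probe sets, so that a shift of the arrays to the same median is not negligible on this scale. Such a shift moves the difference between the diets by the same amount in every probe set, so very small differences can turn by construction. Most probe sets then follow the common offset of the arrays, and a test of a gene list against other genes is set against it. Lists called or lost with this shift are therefore given as values only. Arrays give no count of molecules, and their number limits the precision.

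The 112 control probe sets of the array were left out of the tests. Each remaining probe set was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend), restricted minus supplemented, with Benjamini-Hochberg adjustment over 24016 probe sets and a threshold of 0.05. The prior had 0.483 degrees of freedom beside 4 residual ones, so the variances were hardly moderated. All values were multiplied by a factor of 1e+09 before fitting, because the gene list test otherwise sets a floor on variances that lies above those of this table. Gene symbols came from a platform annotation table, which names 13318 probe sets with 1 gene and 86 with several, and leaves 10724 unnamed. Of the 13292 tested probe sets with 1 gene, 13263 matched a current gene record of the ARS-UCD2.0 annotation by gene identifier and 0 symbols changed. No coordinates are given because no build is named for the array.

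For gene lists, each of 9155 genes was represented by its probe set with the highest mean. The 33 lists, fixed before the data were examined, cover retinoid genes, fat, energy metabolism, muscle fibre types, connective tissue, blood vessels, immune and blood cells, nerve, stress and handling, protein turnover, growth signals and cell division. They were tested with limma's camera at its preset inter-gene correlation of 0.01, two-sided, with adjustment over the 33 lists. Camera sets the genes of a list against the other genes. At the preset it counts them as nearly independent, so its p-values leave out how they vary together from steer to steer. A list score is the mean over a list's genes of each gene's value in SDs over the 6 arrays. Single values such as scores, ages and control ratios were compared with exact two-sided permutation tests, which cannot go below 0.1 with 3 against 3. The arrays hold 3 prime, middle and 5 prime probe sets for 6 bovine housekeeping transcripts, and the 3 prime minus 5 prime difference was compared as a measure of RNA integrity.

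Genes were named by a rule fixed before the data were examined, over probe sets with 1 gene. The first part takes up to 15 genes per direction past the adjusted threshold, without overlap of the groups and with a mean above the median of all probe sets. Where fewer than 12 came from it in a direction, the second part fills up to 12 with the largest differences among probe sets at an unadjusted p under 0.01, with the same 2 conditions, given as values only. The third takes up to 4 members of each list with the smallest unadjusted p, and the fourth 18 genes of fat, retinoid and muscle biology whatever their p. Of these 18, RARB, CYP26B1 and MYH2 have no probe set with 1 gene and are not analysed here. A selection of the genes from the third part is printed.

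The test was tried on simulated data with this number of probe sets and arrays, 200 probe sets being shifted in each simulation. A shift of 5 within-group SDs was recovered in 15.6% of shifted probe sets, 10 SDs in 76.7%, 20 SDs in 96.9% and 40 SDs in 98.9%. With that many shifted probe sets the adjustment is less strict than where 1 changes. A lone change would be recovered less often than these shares. For lists without any shift whose genes had a correlation of 0.4, camera called 35.3% at its preset correlation and 0% with an estimated one. For lists with a shift of 1 SD and that correlation it called 86.4% and 0%.

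Alternatives tried were 2 filters on dim probe sets, quantile normalization, a shift of each array to the same median, a variance prior with trend, array weights, the shared number of the labels as a block, age as a covariate, each array left out, other thresholds, an estimated correlation, the rotation test fry, and the mean of a gene's probe sets. Added after the data were seen were a fit without moderation, camera on ranks, and the retinoid lists without DHRS3. Alternatives for the pseudocount did not apply, since the values are already logarithms. Figures were drawn with matplotlib 3.10.9.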

Results

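The arrays compared muscle of 3 steers that received vitamin A with muscle of 3 steers that did not, after 7 months of fattening. Vitamin A restriction is used in beef cattle during fattening, and retinoic acid, its active form, acts on gene expression through nuclear receptors. Medians of the 6 arrays differed by 8.88e-06 deposited log2 units, more than the whole range of 85.9% of the tested probe sets. Sampled steers were 610.0 ± 9.17 days old in the supplemented group and 598.3 ± 11.4 days in the restricted group (SD, n = 3 each, exact two-sided permutation p = 0.2). The smallest p this design allows in such a test is 0.1.

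**Figure D1:**
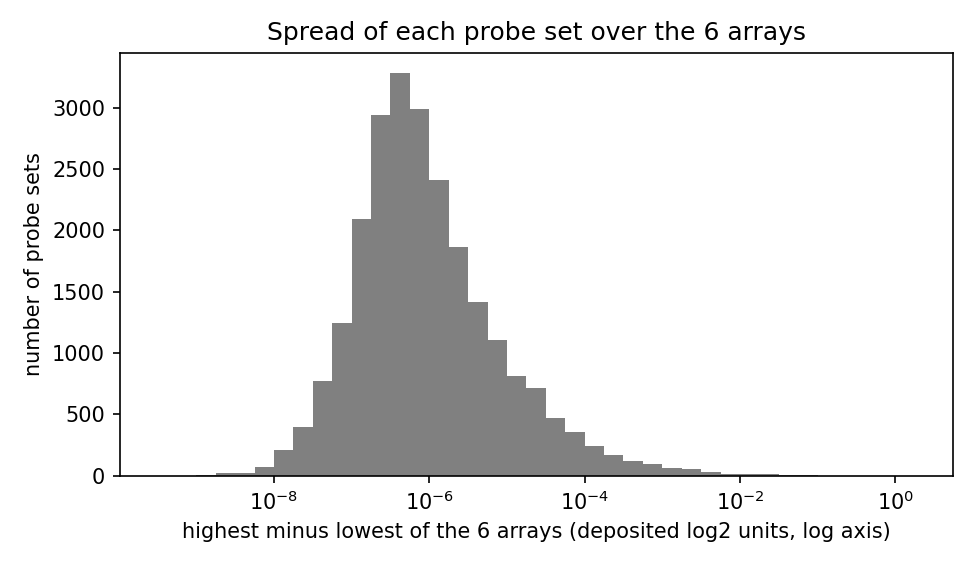
Number of probe sets (vertical axis) by the difference between their highest and lowest array in deposited log2 units (horizontal log axis), for the 24016 tested probe sets. The median difference is 6.77e-07, and 34 probe sets exceed 0.01.

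In the comparison of restricted with supplemented steers, DHRS3, the enzyme that reduces retinaldehyde back to retinol and a gene induced by retinoic acid, was lower in the restricted group. The deposited log2 value of its probe set was 5.874680 ± 7.99e-06 in supplemented and 5.874243 ± 6.38e-06 in restricted steers (SD, n = 3 each). The difference of -0.000437 equals -60.5 within-group SDs, with a limma adjusted p of 0.000794, and all 3 restricted steers lay below all 3 supplemented ones. DHRS3 was the 1 probe set of 24016 past the threshold, 0 probe sets being higher and 1 lower, and the next smallest adjusted p was 0.366. The gap between the groups took up 94.0% of the range of DHRS3, the widest share of any tested probe set in this comparison. The array holds 1 probe set for DHRS3. Without supplemented steer 3 the count was 2, COPB1 of the vesicle coat joining DHRS3 with a limma adjusted p of 0.0129. With age as a covariate the difference of DHRS3 was -0.000436, its SE rose from 5.90e-06 to 8.12e-06 with 3 residual degrees of freedom in place of 4, and its adjusted p of 0.0617 ends the call. The count with quantile normalization was 35 probe sets, 20 higher and 15 lower, but left 15456 probe sets with equal values on all arrays.

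At an unadjusted p under 0.05, 459 probe sets were higher and 522 lower in restricted steers. Their total of 981 compares with 1200.8 from chance, and was 220 with the arrays shifted to the same median. The groups did not overlap in 2103 probe sets, 8.76% of those tested, where chance gives 10%. This too was the fewest of the 10 splits, the others having 2178 to 2655.

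**Figure D2:**
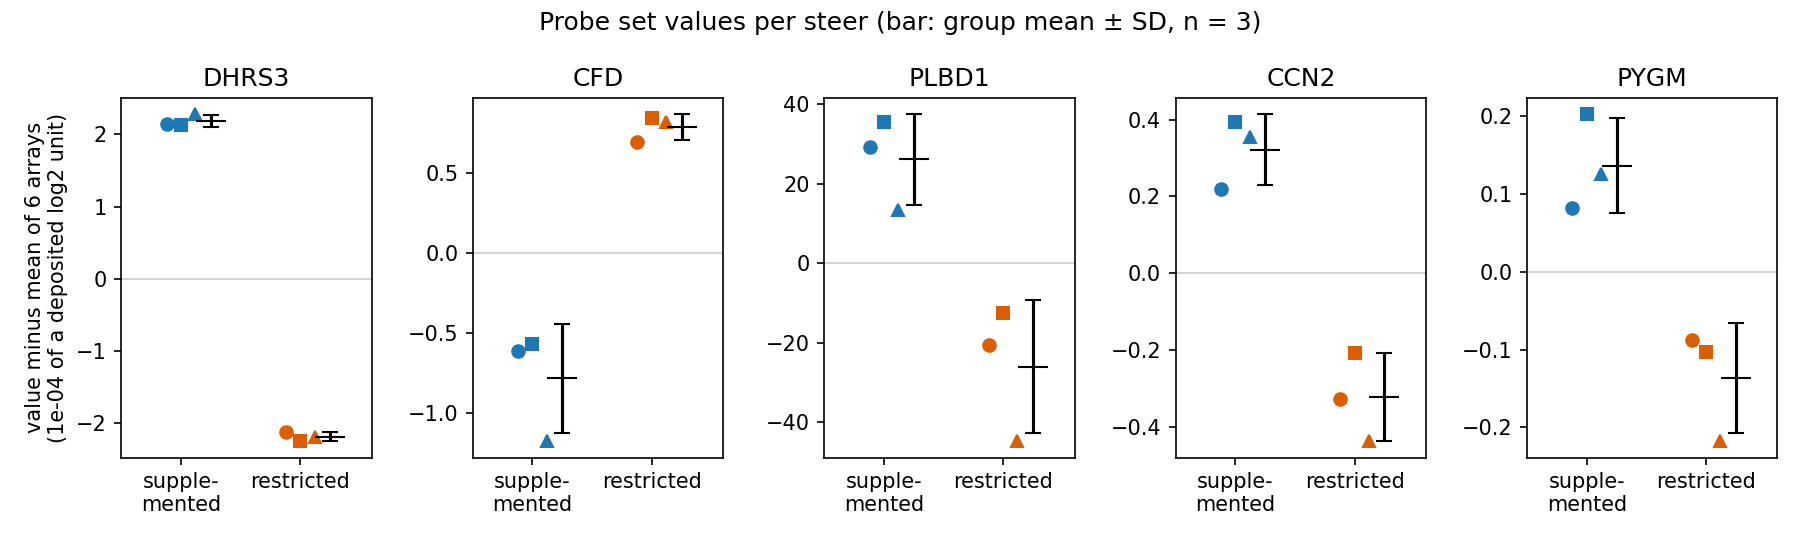
Values of 5 genes in each steer as the difference from the mean of the 6 arrays, in units of 1e-04 deposited log2 (vertical axes, a different scale per gene), by diet (horizontal axis). Circles, squares and triangles are steers 1, 2 and 3 of a group, which are not pairs, and bars are group means ± SD (n = 3). The groups do not overlap in any of the 5 genes, of which DHRS3 alone passed the adjusted threshold.

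None of the other genes named by size passed the adjusted threshold, and their values are given without a call. They are ordered by deposited log2 units, as the rule asks, but the spread of these units differs between probe sets for an unstated reason, so the order is no ranking of effects. On the higher side in restricted steers, CFD, the adipocyte-secreted protease complement factor D, differed by 0.000157 or 6.35 within-group SDs (unadjusted p = 0.000717). It was the 1 adipocyte marker past the threshold when adjusted over the list alone, against 0 over all probe sets. PSMD13, a proteasome subunit, differed by 3.67e-05 or 5.08 SDs, and HSPE1, a mitochondrial chaperonin, by 2.53e-05 or 4.21 SDs. FCGRT, MPC2, GATD3, TUBGCP2, PPID, MMADHC, ACOX3, PARL and FGF1 had differences from 2.42e-06 in FGF1 to 2.21e-05 in FCGRT. MPC2 is a subunit of the mitochondrial pyruvate carrier and ACOX3 a peroxisomal acyl-CoA oxidase. FGF1 has 12 probe sets that do not run in the same direction, and with quantile normalization ACOX3, PARL and FGF1 turned to lower.

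On the lower side, PLBD1 differed by -0.00521 or -3.64 within-group SDs (unadjusted p = 0.00692). CCN2, a matricellular protein also called connective tissue growth factor, differed by -6.44e-05 or -6.22 SDs (unadjusted p = 0.000783) and was the 1 extracellular matrix gene past the threshold adjusted over the list alone. A calmodulin gene listed as CALM differed by -0.000132 or -4.07 SDs. PYGM, the muscle glycogen phosphorylase, differed by -2.73e-05 or -4.13 SDs. MYH1, the myosin heavy chain of fast type IIX fibres, differed by -2.67e-05 or -3.46 SDs. MYH1 has 8 probe sets, of which 6 were lower, and its sequence is close to that of other myosin genes. REEP5, ANKH, SEPHS2, CREBZF, TDRD7 and SIRT5 had differences from -3.92e-05 in REEP5 to -1.74e-05 in SIRT5. SEPHS2 and CREBZF turned to higher with quantile normalization, and another of the 3 probe sets of CREBZF was higher without overlap of the groups, by 7.25e-06. Probe sets of TDRD7, RARA, LEP, PPARGC1A, MYH7, HSPH1 and SOCS3 do not all run in the direction given here either.

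Among retinoid genes, DHRS3 alone passed the test. The list of retinoid uptake, metabolism and receptors had 31 measured genes, 15 higher and 16 lower (camera adjusted p = 0.726), and the list of retinoic acid induced genes had 16, 8 in each direction (camera adjusted p = 0.505). In each of these lists DHRS3 was the 1 gene past the threshold, both adjusted over the list alone and over all probe sets. The mean statistic of the induced genes was negative and their median positive, -4.77 against 0.00727. RBP4, the retinol carrier of plasma, had a value higher by 2.51e-05 or 2.12 SDs. RDH16, a retinol dehydrogenase, had a value lower by -1.28e-07 or -2.68 SDs, BCO1, which cleaves beta-carotene to retinaldehyde, by -3.24e-07 or -2.11 SDs, and HOXA4 one higher by 9.88e-07 or 2.29 SDs that turned to lower with the arrays shifted to the same median. The receptors RARA and RXRG differed by -0.962 and -0.161 SDs and the retinaldehyde dehydrogenase ALDH1A1 by 0.0273 SDs. RARA turned to higher with quantile normalization and ALDH1A1 to lower with the shift.

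Genes of mitochondrial energy metabolism were higher as groups in restricted steers under camera's preset correlation. In oxidative phosphorylation 68 of 76 measured genes were higher (camera adjusted p = 5.76e-10), in fatty acid oxidation 25 of 32 (adjusted p = 5.74e-05) and in the citric acid cycle 18 of 21 (adjusted p = 0.00168). With an estimated correlation these calls ended, at adjusted p = 0.686, adjusted p = 0.686 and adjusted p = 0.798. The citric acid cycle also had an adjusted p = 0.172 without supplemented steer 1 and 0.0967 without restricted steer 2. No single member passed the adjusted threshold over all probe sets. Examples are NDUFV1 of complex I (9.71e-05 or 2.31 SDs), ATP5MC3 of the ATP synthase (0.000105 or 2.18 SDs), the electron transfer flavoprotein subunit ETFA (3.41e-05 or 2.91 SDs, lower with quantile normalization) and SUCLG1 of the citric acid cycle (3.91e-06 or 2.56 SDs). The oxidative phosphorylation score was -0.377 ± 0.943 in supplemented and 0.377 ± 0.252 in restricted steers (SD, n = 3, exact two-sided permutation p = 0.3), with supplemented steer 1 lowest at -1.29 and supplemented steer 3 at 0.595. With quantile normalization fatty acid oxidation and the citric acid cycle turned to lower.

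Glycolysis and glycogen genes and fast fibre genes were lower as groups in restricted steers under the preset correlation. Of 26 measured genes of glycolysis and glycogen 19 were lower (camera adjusted p = 0.00155), and of 16 fast fibre genes 12 were lower (adjusted p = 0.00989). With an estimated correlation both had an adjusted p = 0.656. HK1 differed by -3.59 SDs, and the highly expressed muscle enzymes PGAM2 and TPI1 by -1.92 and -1.80 SDs. PGAM2, PYGM, ENO3 and FBP2 were put on both lists when these were fixed. FBP2 went the other way, higher in restricted steers by 0.000192 without overlap of the groups (limma unadjusted p = 0.0864). Scores of the glycolysis list were 0.290 ± 0.246 and -0.290 ± 0.249, and those of the fast fibre list 0.287 ± 0.256 and -0.287 ± 0.0972, in supplemented and restricted steers (SD, n = 3). Neither score overlapped between the groups, at the smallest exact permutation p of 0.1. Chance gives no overlap in 10% of lists. Over all lists tested, brown and beige fat and smooth muscle and pericyte scores also reached this p, and no others did. Lack of overlap was thus about as frequent as chance gives, and adds no independent support to lists picked by camera on the same arrays. The glycolysis and fast fibre lists turned to higher with quantile normalization. With each array shifted to the same median their adjusted p values were 0.488 and 0.0826. The fast fibre list had an adjusted p = 0.0604 without supplemented steer 2, 0.0890 without restricted steer 2 and 0.0638 with age as a covariate. Slow fibre genes were not past the threshold (9 of 16 higher, camera adjusted p = 0.726). With the arrays shifted to the same median they were called higher (adjusted p = 0.000185), given as a value only. MYH7, the slow myosin heavy chain, differed by 0.181 SDs.

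Adipocyte markers were higher as a group in restricted steers under the preset correlation, with 22 of 24 measured genes higher (camera adjusted p = 0.000227), and had an adjusted p = 0.686 with an estimated correlation and 0.0746 with age as a covariate. Beside CFD, the fatty acid transporter CD36 differed by 0.000918 or 1.88 SDs, the adipokine ADIPOQ by 7.57e-05 or 1.78 SDs and the lipid droplet protein CIDEA by 0.00103 or 1.78 SDs. PPARG, the main transcription factor of fat cells, differed by 1.41 SDs, FABP4 by 0.971, LEP by 0.512 and CEBPA by 0.437 SDs, the last 2 turning to lower with the arrays shifted to the same median. The score was -0.355 ± 0.496 in supplemented and 0.355 ± 0.748 in restricted steers (SD, n = 3, exact two-sided permutation p = 0.3), with restricted steer 2 at -0.486, below 2 of the 3 supplemented steers. The list of brown and beige fat genes, 6 of 7 higher, had a camera adjusted p = 0.0375, an adjusted p = 0.656 with an estimated correlation, and values from 0.0562 without supplemented steer 3 to 0.235 without restricted steer 1 when any single steer was left out. It also missed the threshold with age as a covariate (0.158) and with probe sets above the median (0.0572) or the first quartile of level (0.0643). Its members COX7A1 (1.08 SDs) and PPARGC1A (0.969 SDs, lower with that shift) are energy metabolism genes that muscle expresses too. CIDEA, at 1.78 SDs, is also on the adipocyte list. Fatty acid and triglyceride synthesis was not past the threshold, with 18 of 25 higher (camera adjusted p = 0.0904). With the arrays shifted to the same median its adjusted p was 2.43e-10, but most genes it is set against then share the arrays' offset. The list was called higher with array weights (0.0396), without supplemented steer 1 (0.00621) and without restricted steer 2 (0.00318), and turned to lower without supplemented steer 2 (0.911). In it DGAT2 differed by 2.07 and GPAM by 1.76 SDs, SCD by 0.486 and FASN by 0.294 SDs.

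**Figure D3:**
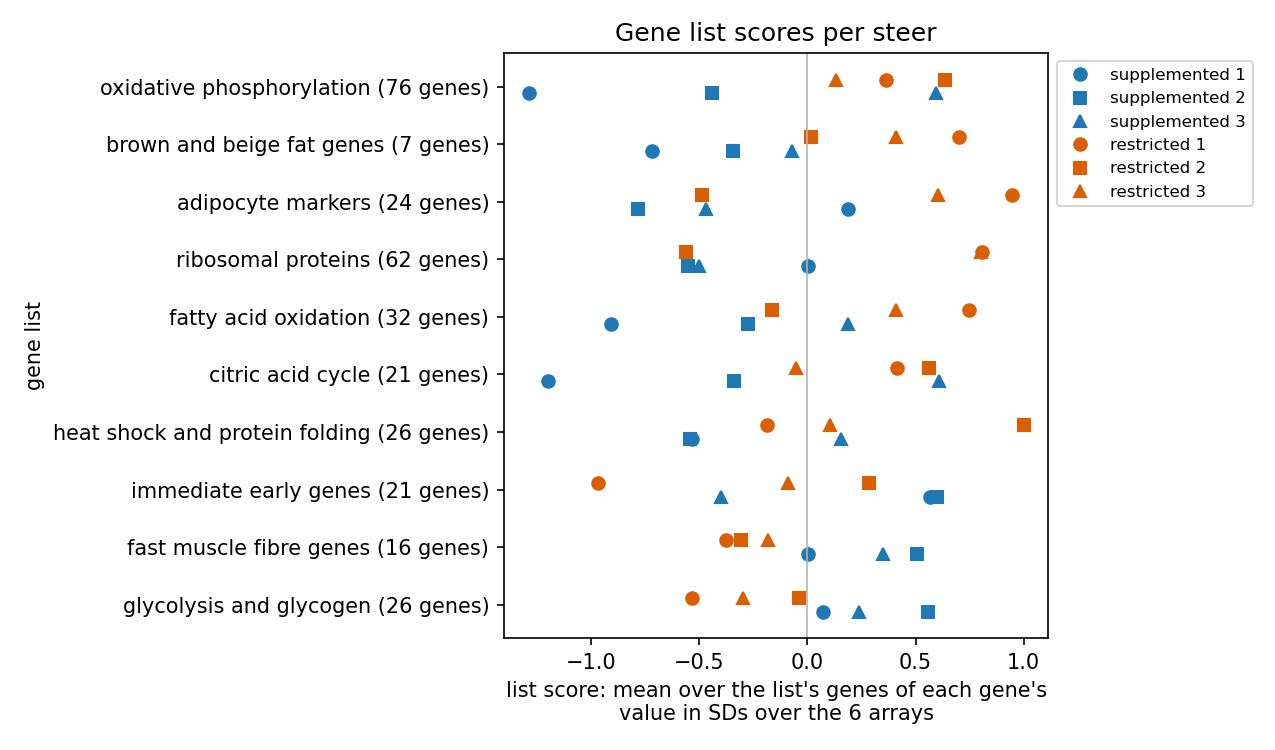
Scores of the 10 gene lists past the threshold with camera's preset correlation (vertical axis), each the mean over the list's genes of the value in SDs over the 6 arrays (horizontal axis). Each point is 1 steer, coloured by diet. The groups overlap in 7 lists and do not in brown and beige fat, fast fibre, and glycolysis and glycogen genes, and 4 of the 10 directions turn with quantile normalization.

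Of the 4 lists chosen as signs of handling and RNA quality, 3 were past the threshold under the preset correlation. Circadian clock genes were not (4 of 7 higher, camera adjusted p = 0.543). Ribosomal protein genes were higher in restricted steers under the preset correlation (52 of 62, camera adjusted p = 4.22e-08; adjusted p = 0.686 with an estimated correlation), RPL10 by 0.000135 or 2.80 SDs and RPL35 by 1.41e-06 or 4.56 SDs, which turned to lower with the arrays shifted to the same median. Heat shock and protein folding genes were higher too (21 of 26, adjusted p = 0.000481; adjusted p = 0.686 with an estimated correlation), among them HSPD1 by 2.27, HSPH1 by 2.12 and the small heat shock protein HSPB8 by 2.09 SDs. Immediate early genes, which respond to stress and handling within minutes, were lower (17 of 21, adjusted p = 0.0375; adjusted p = 0.827 with an estimated correlation), with DUSP1 at -1.44 SDs and SOCS3 at -1.93 SDs. The heat shock list had an adjusted p = 0.188 without restricted steer 2. The immediate early list had 0.385 and 0.265 without supplemented steers 1 and 2, 0.696 and 0.0579 without restricted steers 1 and 3, 0.0638 with age as a covariate and 0.675 with the arrays shifted to the same median. It also missed the threshold with probe sets above the median (0.0572) or the first quartile of level (0.0673) and with the mean of a gene's probe sets (0.0824), and its score difference was -0.512 without and -0.532 with age in the model. The 3 prime minus 5 prime differences of the 6 housekeeping controls gave exact two-sided permutation p values from 0.4 for eIF-4E to 0.9 for actin. They share the narrow spread of the deposited values, GAPDH running from 0.238764 to 0.238768 over the 6 arrays. Whether RNA integrity differed between the diets is thus not settled by them.

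In all, 10 of 33 lists were past the threshold with the preset correlation, 7 higher and 3 lower, and 0 with an estimated one, where the smallest adjusted p was 0.656. By fry, which tests whether a list's genes move on balance in 1 direction, the 2 retinoid lists passed and no other. Without DHRS3 neither passed, with both at a fry adjusted p of 0.983. Of the lists of other cells, none was past the threshold in the test as planned, but several were under alternatives. Adjusted p values as planned are given for markers of preadipocytes (adjusted p = 0.525), extracellular matrix (0.726), endothelium (0.505), smooth muscle and pericytes (0.0904), macrophages (0.391), lymphocytes (0.543), red blood cells (0.709) and nerve (0.129). Smooth muscle and pericyte markers were called higher on ranks (0.0469) and, as a value only, with the arrays shifted to the same median (1.82e-05). Extracellular matrix and macrophage genes were called lower with age as a covariate (0.0156 and 0.0161). Extracellular matrix was called higher without supplemented steer 1 (0.00240) and lower without supplemented steer 2 (0.00600). Without supplemented steer 3, macrophage (0.0290), lymphocyte (0.0102) and nerve markers (0.0498) were called lower. CD34, a marker of progenitor and endothelial cells, differed by -2.65 SDs, the myelin gene MBP by -3.15 SDs, COL6A2 by 3.14 SDs (lower with quantile normalization and with the arrays shifted to the same median) and LAMB1 by 2.31 SDs.

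Other lists not past the threshold in the test as planned were myogenic factors (adjusted p = 0.391), antigen presentation (0.525), interferon response (0.505), atrophy, ubiquitin and autophagy genes (0.911), proteasome subunits (0.726), growth hormone, insulin and IGF signalling (0.997), cholesterol synthesis (0.297), TGF-beta, BMP and Wnt signalling (0.876), antioxidant and glutathione genes (0.726) and the cell cycle (0.110). Proteasome subunits were called higher without supplemented steer 3 (0.0168) and without restricted steer 1 (0.0208), and cholesterol synthesis without supplemented steer 1 (0.0471). With the arrays shifted to the same median, proteasome subunits (5.29e-05) and antioxidant genes (0.00794) were called higher, as values only. The myogenic factor MYOG differed by 2.51 SDs, which turned to lower with that shift, and MSTN, the inhibitor of muscle growth, by -1.06 SDs. PSMD13 was the 1 proteasome gene past the threshold adjusted over the list alone. Mean and median statistics of the proteasome, circadian clock and antioxidant lists had opposite signs.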

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

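The fit without moderation, camera on ranks and the retinoid lists without DHRS3 were chosen after the data were seen, the other alternatives before. DHRS3 was lower under every alternative run, with a difference from -0.000440 to -0.000340. Its limma adjusted p ran from 0.00991 to 0.0492 when single steers were left out, and apart from the replicate block, given next, it missed the threshold only with age as a covariate (0.0617), which spends a residual degree of freedom. Leave-one-out counts of changed probe sets ran from 1 to 2, and of probe sets higher in restricted steers from 0 to 1. Differences this small against an unknown scale cannot be turned into folds. The planned threshold of an unadjusted p under 0.01 and at least 1.5-fold gave 0 changed and 0 lower by construction, since only 1 probe set ranged over more than 0.1. The pseudocount alternatives were not run because the values are logarithms.

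The shared replicate numbers carry no stated pairing. Deviations of same-numbered steers correlated at 0.0374, 0.0151 and 0.0152 over probe sets, none above 0.1, although each steer correlated best with its own number. With the replicate block 0 probe sets were changed and 0 lower, DHRS3 having an adjusted p of 0.521 with 2 residual degrees of freedom. Fatty acid and triglyceride synthesis (0.00933) and smooth muscle and pericyte markers (0.0488) were then called higher, and brown and beige fat (0.0657) and immediate early genes (0.197) were not called. The retinoid uptake list turned to higher at an adjusted p of 0.824, slow fibre genes to lower at 0.983, and TGF-beta, BMP and Wnt genes to higher at 0.980.

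Counts that moved by over 1.5 times were as follows. At an unadjusted p under 0.05, there were 442 among probe sets above the median level, where fewer were tested, 220 with arrays shifted to the same median and 44 with quantile normalization. Quantile normalization gave 35 changed probe sets, 20 higher and 15 lower, and 0 lists, after making 15456 probe sets and 40 of the named genes equal on all arrays. With age as a covariate 0 probe sets were changed and 0 lower. An estimated correlation gave 0 lists, fry 2, and fry without DHRS3 in the retinoid lists 0. Of the 10 lists called, quantile normalization turned 4. With the arrays shifted to the same median 12 lists passed, of which 7 were among these 10. Most genes share the arrays' offset after that shift, so these counts decide nothing.

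Directions that turned are given next. The cause was not tested, but for single genes under the shift to the same median it follows from the arithmetic. With quantile normalization each value is replaced by the mean at its rank, so differences take the size of the steps between ranks. The difference of NDUFB3 went from 7.81e-06 to -0.00307. Turns under that normalization are given as values only. Quantile normalization turned fatty acid oxidation, citric acid cycle, glycolysis, slow and fast fibre, macrophage, lymphocyte, red blood cell and antioxidant lists, each at an adjusted p of 0.992. It turned SEPHS2 (1.33e-05), CREBZF (2.73e-05), ACOX3 (-9.88e-06), PARL (-3.41e-05), FGF1 (-8.29e-05), ETFA (-0.000433), NDUFB3 (-0.00307), COL6A2 (-5.39e-05), LEP (-2.08e-05) and RARA (2.04e-05). The shift to the same median turned the preadipocyte list (adjusted p 0.488), extracellular matrix (0.236), atrophy genes (0.236) and TGF-beta, BMP and Wnt genes (0.504). It turned HOXA4 (-1.24e-06), HADHA (-1.64e-07), RPL35 (-8.19e-07), PPARGC1A (-7.24e-07), MYOG (-7.36e-07), COL6A2 (-1.67e-06), CEBPA (-1.99e-06), LEP (-8.56e-07) and ALDH1A1 (-1.55e-06). That shift moved the difference of every probe set down by the same amount, in DHRS3 from -0.000437145 to -0.000439369. Positive differences smaller than this amount turn by construction, which says nothing about their spread between steers. Age as a covariate turned CEBPA (-1.49e-07), slow fibre (adjusted p 0.252), myogenic (0.564), endothelial (0.733) and atrophy lists (0.836). Atrophy genes also turned above the median level (0.839), with array weights (0.946) and with the mean of a gene's probe sets (0.855). TGF-beta, BMP and Wnt genes turned above the median level (0.647), and growth hormone, insulin and IGF genes with the trend prior (0.968) and the mean of probe sets (0.452). Without DHRS3 the retinoid uptake list (0.752) and the retinoic acid induced list (0.797) turned to higher, as both did in fry (0.983), and the uptake list did on ranks (0.968). The 3 prime minus middle difference turned for actin (exact permutation p = 0.9), GAPDH (0.6), EF1A (0.9) and eIF-4E (0.2).

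When single steers were left out, these lists turned in at least 1 case, with adjusted p from the lowest to the highest of the 6 cases. Antigen presentation had 0.0638 to 0.877, antioxidant genes 0.281 to 0.936, atrophy genes 0.576 to 0.958, endothelial markers 0.0765 to 0.858, extracellular matrix 0.00240 to 0.792 and fatty acid and triglyceride synthesis 0.00318 to 0.911. Growth hormone, insulin and IGF genes had 0.212 to 0.808, interferon response 0.210 to 0.960, lymphocytes 0.0102 to 0.976, macrophages 0.0290 to 0.719, preadipocytes 0.187 to 0.775, proteasome subunits 0.0168 to 0.863, retinoid uptake 0.395 to 0.936, slow fibre genes 0.307 to 0.960 and TGF-beta, BMP and Wnt genes 0.152 to 0.958. Differences ran from -1.17e-05 to 1.66e-05 in ALDH1A1, -0.00448 to 0.00875 in FASN, -8.28e-08 to 2.82e-06 in LEP, -0.000104 to 0.000174 in MYH7, -1.20e-07 to 1.08e-07 in RXRG and -0.00162 to 0.0102 in SCD. Some fat and mitochondrial genes kept their direction but moved widely. The ranges were 0.00333 to 0.0136 in FABP4, 9.17e-09 to 6.55e-07 in CEBPA and 0.000545 to 0.00114 in CD36. They were 1.52e-05 to 7.02e-05 in COX7A1 and 4.23e-07 to 2.14e-06 in PPARGC1A. The exact permutation p of the control ratios ran from 0.4 to 1 for actin and GAPDH and 0.5 to 1 for cyclophilin. For controls that did not turn, it ran from 0.1 to 0.8 for eIF-4E, lowest without restricted steer 1. It ran from 0.2 to 1 for EF1A and 0.4 to 0.9 for GST.

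Over all alternatives, 987 comparisons of a named gene kept direction and side of the threshold, 2 lost the call and 30 turned. DHRS3 alone was called in the main fit, so the 2 lost calls are its own, with the replicate block and with age. The other named genes had no call to lose, and for them the tally mainly counts directions. Both level filters, the trend prior, the fit without moderation and the replicate block leave each difference unchanged by construction. DHRS3 differed by -0.000437145 in each of them and in the main fit. Kept gene directions under these settings are therefore no sign of stability. The shift to the same median lowers every difference, so genes lower in restricted steers cannot turn under it. Of the comparisons of a list, 510 kept both, 69 lost the call, 23 gained it and 62 turned, of which 4 also lost and 1 also gained the call.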

Other observations

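The tests of the retinoic acid induced genes without DHRS3, of the correlation within lists, of the correlation of adipocyte markers and of a lower share of muscle fibres were chosen after the result was seen, as was the choice of the most variable genes. The 100 genes with the widest range over the 6 arrays, of 9155, held 10 of the 25 measured genes of fatty acid and triglyceride synthesis, where chance gives 0.273 (hypergeometric adjusted p = 1.44e-12). They included FASN, ACLY, SCD, ELOVL6 and THRSP, enzymes and a regulator of fat synthesis. They also held 9 extracellular matrix genes such as COL1A2, COL3A1 and FN1 (adjusted p = 2.00e-08) and 6 adipocyte markers such as FABP4 and CIDEC (adjusted p = 1.84e-06). Preadipocyte markers and immediate early genes had 4 each (both adjusted p = 0.000459), and atrophy and heat shock genes 3 each (both 0.0129), of which the immediate early and heat shock lists were chosen as signs of handling. The widest range was that of the immediate early gene FOS at 0.261, followed by THRSP at 0.0775 and DDIT4, a stress-induced inhibitor of growth signalling, at 0.0703. The diets did not overlap in 7 of the 100, where chance gives 10%. Ranges depend on the authors' unstated normalization, and genes of a list are not independent, so these p-values are descriptive.

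DHRS3 was lower in restricted steers. Of the 10 splits of the 6 arrays into 3 and 3, the real one gave 1 changed probe set and the highest other gave 0, so 1 split gave as many, and 10 splits are too few for a share under 0.05. At an unadjusted limma p under 0.05 the real split had the fewest probe sets of the 10, 981. Gaps as wide a share of the range occurred in 2 probe sets over the other 9 splits, ADH1C and EED, but ADH1C varies by the last stored digit alone, so its gap is fixed by rounding and counts for nothing. EED has a range of 1.30e-07, and the effect of the normalization on such gaps stays open. A sequence variant under the probes could not be tested, since the array holds 0 other DHRS3 probe sets. Lower retinoic acid signalling in restricted muscle is a candidate explanation, but no shift of the other 15 retinoic acid induced genes was found (camera p = 0.736 with an estimated correlation), which leaves it open.

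For 7 of the 10 called lists the shift may come from genes that vary together from steer to steer, since their estimated correlations were 0.256 or more. For fast fibre (-0.0178), brown and beige fat (-0.0138) and glycolysis genes (0.0549) the estimates give no sign of it, though they rest on 4 residual degrees of freedom and decide nothing. For the 7 lists the loss of the calls with an estimated correlation decides nothing. In the simulation at a correlation of 0.4 that test called 0% of shifted lists and 0% where no list was shifted. Of uncorrelated lists shifted by 1 SD it recovered 63.2%, against 98.2% at the preset correlation. That share pools lists of different sizes. Fast fibre and brown and beige fat genes, with 16 and 7 measured genes, were not among the shifted lists. It therefore does not tell how often such a shift would have kept the calls of the other 3 lists. The simulated shift was not matched to the observed lists, and a shift by diet is not excluded. Of the 10 splits, 6 gave at least 10 lists, the real one with its 10 included, and the highest other gave 12. The count of called lists in the real split is thus no larger than splits that mix the diets often give. A share under 0.05 could not have been reached with 10 splits. Splits that mix the diets reached a camera p of 5.96e-22 for oxidative phosphorylation and 3.18e-12 for adipocyte markers, against 1.74e-11 and 2.75e-05 in the real split. With age as a covariate 6 of the 10 lists passed in the same direction at the preset correlation, and with the wide errors of 3 steers per group age stays open. Score differences shrank with age for adipocyte markers (0.710, SE 0.518, to 0.524, SE 0.703), fast fibre genes (-0.574, SE 0.158, to -0.411, SE 0.148), glycolysis and glycogen (-0.579 to -0.481) and, slightly, ribosomal proteins (0.699 to 0.683). They grew for oxidative phosphorylation (0.755, SE 0.564, to 1.11, SE 0.705), fatty acid oxidation (0.664 to 0.903), the citric acid cycle (0.618 to 0.885), heat shock (0.612 to 0.754), brown and beige fat (0.752 to 0.875) and immediate early genes (-0.512 to -0.532). An effect of the diet on fibre type and mitochondria is a further open explanation.

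Adipocyte markers were called higher in restricted steers at the preset correlation alone, with an adjusted p = 0.686 with an estimated correlation and 0.0746 with age as a covariate. Samples could hold different amounts of fat tissue, but the estimated correlation of 0.424 between the markers does not single this out, since 13 of 33 lists exceeded 0.2 and proteasome subunits reached 0.561; the bar of 0.2 set first was raised after the value was seen. A lower share of muscle fibres would raise markers of other tissues alike, and the adipocyte score minus the extracellular matrix score differed by 0.778 between the diets (SE 0.377, exact two-sided permutation p = 0.2), which is over 2 SE from 0. The bar of 2 SE set first would have spoken against this explanation; it was tightened after the value was seen, to ask also for the smallest possible permutation p, and the explanation is left open. An effect of vitamin A restriction on fat cells cannot be told apart from these.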
